A study of Mus musculus with 8 samples.

How the data were processed

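Total RNA from sorted CD22-positive, B220-positive spleen cells of 4 Sca1-HGAL and 4 wild-type samples was measured on Affymetrix Mouse Gene 1.0 ST arrays, per the labels. Groups and replicate numbers were taken from the sample titles. The deposited values are intensities that the authors made with RMA, per the submitters' processing notes, which corrects background, normalises between arrays and summarises probes. The version, the annotation and the genome build are not given in the sources used here. The values were on a linear scale, with a lowest value of 4.94 and a highest of 24302, and log2 was taken here with no pseudocount and no filter. The design had assumed deposited log2 values and named this step for linear ones. RMA draws arrays to a common distribution, so a change shared by most genes would be removed, and it shrinks folds of dim probe sets. No pair of columns shared more than 0.060% of equal values, and no sample was left out.

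Of 34760 probe sets, the platform table paired 21640 with 1 gene symbol, 1321 with several and did not list 11799. The 21640 were tested and stand for 19937 genes, 954 of them with several probe sets. A gene was represented by the probe set with the highest mean over all arrays. Of the probe sets, 21553 matched a gene identifier in the mouse reference gene table (GRCm38.p6), which changed 0 symbols and was otherwise used only for chromosome names and gene order.

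Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no covariate, two-sided, Benjamini-Hochberg adjusted p under 0.05). Gene lists, 33 with 535 different genes of which 480 were measured, were tested with camera at a preset correlation of 0.01 and adjusted over the lists. A list symbol that is no current symbol in the reference table was matched through its synonyms there, which applied to 2 genes, Atp5a1 and Atp5b. The tests, the lists and the naming rule were fixed before the data were examined. The rule named up to 12 genes per direction past the threshold by fold, then, up to 12, those with the smallest p whose groups did not overlap. It added up to 4 members with the smallest p per list and a fixed set of B-cell, strain and sex genes, and passed over unnamed predicted genes, 1 in each direction. Exact permutation tests of list scores used all 70 assignments of the 8 arrays. A simulation drew independent normal values from each probe set's mean and its limma SD (21640 probe sets, 10 draws), with changes added to 200. There limma recovered 98% of genes changed by 1 on the log2 scale and 99.7% of those changed by 2, with 5.3% false calls. Differences between arrays that many genes share were not simulated, so these shares do not give the power in these data. Among 19937 genes simulated as independent, a shift of 0.4 in the marginal zone B list alone was called by camera in 10 of 10 draws. The members of the real lists vary together, so this does not test the preset correlation of 0.01.

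The alternatives were a second quantile normalisation, median centring, filters on dim probe sets, array quality weights, a block for the replicate number, a trended robust prior, an ordinary test, other thresholds, all rows, the mean of a gene's probe sets, other list tests and leaving out each array. Added after seeing the data were leaving out the 2 arrays with high Xist, Xist as a covariate, and the permutation test of list scores. The labels give no batch, litter or sex.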

Results

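Splenic B cells of adult mice carrying the human germinal centre gene HGAL under the Sca1 (Ly6a) promoter were compared with those of wild-type littermates. The labels call these mice knock-in in one field and transgenic in another. HGAL, also called GCET2 or GCSAM, is an adaptor protein of germinal centre B cells. The series title ties it to B-cell receptor signalling through the kinase Syk, lymphoid hyperplasia and amyloidosis. Cells positive for both CD22 and B220 were sorted from spleens on a mixed CBA and C57BL/6J background. Total RNA of 4 Sca1-HGAL and 4 wild-type samples was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample. The median deposited intensity of an array ranged from 148.7 to 157.2. Precision is limited by the 4 arrays in each group. The labels do not say whether each array is a separate mouse, so p-values measure the spread between these samples. Levels below are log2 intensities with their SD over 4 arrays, and log2 folds are Sca1-HGAL minus wild-type with the standard error (SE).

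The sorted cells had high levels of B-cell genes in both groups. Cd79a, part of the B-cell receptor, was at 13.40 ± 0.07 (SD, n = 4) in wild-type and 13.29 ± 0.03 (SD, n = 4) in Sca1-HGAL arrays. Cd22, one of the sorting markers, was at 12.66 ± 0.04 and 12.70 ± 0.13. The gene of the other marker, Ptprc, was at 12.77 in both groups. These levels do not show how pure the sort was. In wild-type arrays, 15 of 16 T cell, 16 of 19 macrophage and monocyte, 7 of 11 NK cell and 11 of 15 neutrophil list genes were above log2 6. Cd3e of the T cell list was at 8.72 in wild-type and 8.81 in Sca1-HGAL arrays, Cd68 of the macrophage list at 9.29 and 9.38. The mouse counterpart of HGAL, Gcsam, had a log2 fold of -0.29 (SE 0.17, limma adjusted p = 0.62), and its mouse probes are no sure measure of human HGAL. The arrays therefore give no check of HGAL expression. Ly6e, another gene of the Ly6 family, had a log2 fold of -0.42 (SE 0.35, adjusted p = 0.75). Ly6a was not analysed here.

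St3gal5 fell in Sca1-HGAL B cells and was the single probe set of 21640 that passed limma at an adjusted p under 0.05. St3gal5 encodes the sialyltransferase that makes ganglioside GM3. Its level was 9.16 ± 0.18 (SD, n = 4) in wild-type and 7.33 ± 0.20 (SD, n = 4) in Sca1-HGAL arrays, a log2 fold of -1.84 (SE 0.12, adjusted p = 0.00048). All 4 Sca1-HGAL arrays lay below all 4 wild-type arrays. Bmpr1a, a receptor for bone morphogenetic proteins, came next, with a log2 fold of 2.50 (SE 0.28) and an adjusted p = 0.051, just short of the threshold. Its level was 5.34 ± 0.19 in wild-type and 7.84 ± 0.69 in Sca1-HGAL arrays. The wild-type level was under log2 6 and the values carry no detection calls, so the size of this fold is uncertain. Bmpr1a passed with median centring (adjusted p = 0.041), array weights (0.016), the replicate block (0.039) and without Sca1-HGAL replicate 3 (0.00029). It passed in no other setting, with an adjusted p = 0.264 without the 2 arrays with high Xist. At an adjusted p under 0.10, 9 probe sets passed, 3 higher and 6 lower. Without Sca1-HGAL replicate 3, 40 probe sets passed, 26 higher and 14 lower. That array had a mean correlation over probe sets of 0.993 with the wild-type arrays and 0.991 with its own group. On the first principal component it was at -7.22, within the wild-type range of -11.78 to -6.17, with the other Sca1-HGAL arrays at 2.66 to 27.68. With an ordinary test without variance sharing, none passed, with an adjusted p = 0.165 for St3gal5.

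**Figure D1:**
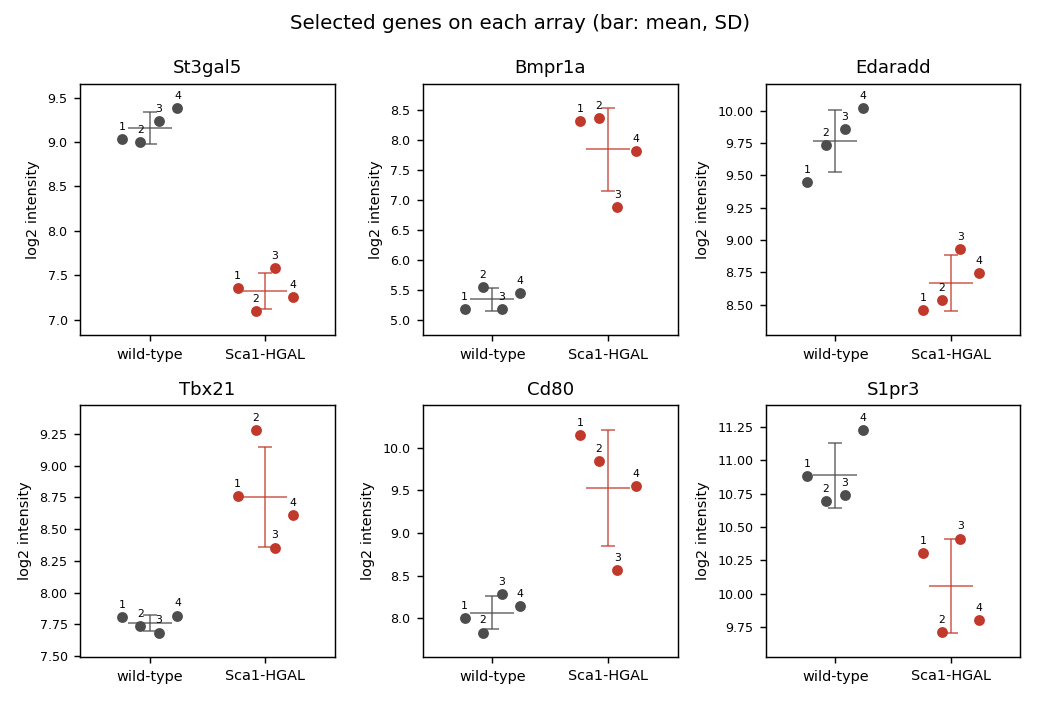
Log2 intensity (vertical axes) of 6 genes on the 4 wild-type and 4 Sca1-HGAL arrays, with replicate numbers beside the points and bars for the mean and SD. St3gal5 is near 9.16 in wild-type and 7.33 in Sca1-HGAL arrays, and the groups do not overlap for any of the 6 genes.

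The next genes by p, all separated between the groups and none past the threshold, are given by value. On the lower side, Edaradd, an adaptor of ectodysplasin receptor signalling, had a log2 fold of -1.10 (SE 0.13, limma adjusted p = 0.073). Asah1, a lysosomal acid ceramidase, had -0.64, Ifi208, a member of the interferon-inducible Ifi200 family, -1.20, and Asb2 -0.78, each at an adjusted p = 0.098. Lpar2, a lysophosphatidic acid receptor, had -0.77, Tmem26 -0.79, Rgl1 -0.75, Pik3r4 -0.54, Plekhg3 -0.38 and Tex2 -0.38, at an adjusted p = 0.111, and Rnpep -0.79 at 0.119. On the higher side, Lpgat1 had a log2 fold of 0.47 and Rcan3, a calcineurin regulator, 0.49, both at an adjusted p = 0.098. Tbx21, which encodes the transcription factor T-bet, had 0.99, Cdk10 0.71, Glt28d2 0.63, the innate sensor gene Nod1 0.58, Tspyl5 0.44, the cytokine signalling inhibitor Socs3 0.37 and Sdr42e1 0.35, each at 0.111. Cdk14 had 1.36 and Zfp287 0.51, at 0.116. Second probe sets of Cdk10 and Socs3 had log2 folds of 0.08 and 0.07.

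More probe sets had an unadjusted p under 0.05 than the mean expected by chance, 2075 against 1082, with 1196 higher and 879 lower. Probe sets vary together, and another split of the 8 arrays gave 1992, so chance is not excluded. The 4 Sca1-HGAL arrays lay wholly above or below the wild-type arrays for 5.45% of probe sets, against 2.86% by chance.

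Among 33 gene lists fixed before the data were examined, genes of marginal zone B cells were lower in Sca1-HGAL arrays. Marginal zone B cells are a splenic subset that answers blood-borne antigen. The median log2 fold of the 17 members was -0.45, and 15 members had a negative value, 11 of them at an unadjusted p under 0.05. Asb2 had -0.78 (SE 0.11), Myof -0.73 (SE 0.15), the chemokine receptor gene Ackr3 -0.58 (SE 0.11) and Pik3r4 -0.54 (SE 0.09). S1pr3, a sphingosine-1-phosphate receptor, had -0.83 (SE 0.17), and Cr2, the complement receptor CD21, -0.28 (SE 0.12). No member passed over all genes tested, and 10 passed when adjusted over the list alone. The list score, the mean log2 level of its members, was 10.06 ± 0.15 (SD, n = 4) in wild-type and 9.62 ± 0.09 (SD, n = 4) in Sca1-HGAL arrays. The list passed limma's camera with a preset correlation of 0.01 (adjusted p = 5.9e-14) but not with an estimated correlation (adjusted p = 0.264). It also passed fry (adjusted p = 0.041).

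Genes of B-1 and age-associated B cells were higher in Sca1-HGAL arrays. These are an innate-like B-cell subset and a T-bet-positive population that gathers with age. All 15 members had a positive log2 fold, from 0.06 to 1.46, with a median of 0.95, and 12 had an unadjusted p under 0.05. Cd80, a costimulatory ligand, had 1.46 (SE 0.28), and its second probe set 1.31. Tbx21 had 0.99 (SE 0.16), Zbtb20 0.95 (SE 0.19) and Ahnak 0.70 (SE 0.14). Itgam and Itgax, which encode CD11b and CD11c and were chosen after their values were seen, had 0.99 (SE 0.26) and 0.48 (SE 0.12). No member passed over all genes tested, and 12 passed when adjusted over the list alone. The score was 8.08 ± 0.07 (SD, n = 4) in wild-type and 8.91 ± 0.50 (SD, n = 4) in Sca1-HGAL arrays, from 8.30 in replicate 3 to 9.45 in replicate 1. The list passed camera (adjusted p = 5.9e-14) but neither camera with an estimated correlation (adjusted p = 0.378) nor fry (adjusted p = 0.115). In the Sca1-HGAL arrays the neutrophil score was also lowest in replicate 3, at 6.20, and highest in replicate 1, at 7.17, with a difference between the groups of 0.42. The T cell score was 7.09 and 8.02 on these arrays, with a difference between the groups of 0.03, and the NK cell score 5.87 and 6.60, with a difference of -0.15. Itgam is also expressed by myeloid and NK cells, and Tbx21 by NK cells.

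**Figure D2:**
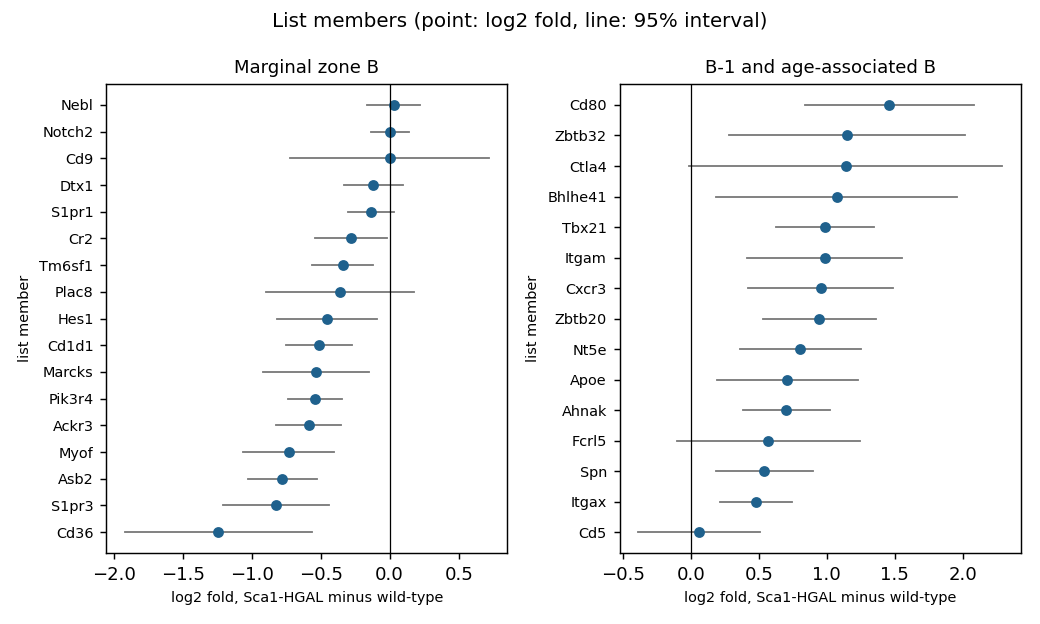
Log2 fold (horizontal axes, Sca1-HGAL minus wild-type, n = 4 and 4) of each measured member of the marginal zone B and the B-1 and age-associated B lists, as points with lines for the 95% interval. In the first, 15 of 17 members lie below 0, and in the second all 15 lie above it.

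For both lists, the 4 Sca1-HGAL scores lay apart from the 4 wild-type scores, which gives an exact two-sided permutation p = 0.0286, the smallest that 8 arrays allow. The immunoglobulin constant region, MHC class II and costimulation, and BCL2 family lists were separated in the same way, so 5 lists had this p. The MHC class II and costimulation list shares Cd80, its member with the smallest p, with the B-1 and age-associated list. Adjusted over the 33 lists, the p of 0.0286 became 0.189, and no list could pass unless most lists shared this smallest value. Camera with the preset correlation called 14 lists, 2 higher and 12 lower, and with an estimated correlation 0. After a second quantile normalisation it called 10, 3 higher and 7 lower. Without Sca1-HGAL replicate 2 or 4 it called 7, and without wild-type replicate 1 or 3 it called 9. Another split of the 8 arrays called 15.

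Interferon response genes were lower on average in Sca1-HGAL arrays, with a median log2 fold of -0.41 over 19 measured members, 18 of them negative. Ifit3 had -0.81 (SE 0.29), Rtp4 -0.74 (SE 0.25), Cmpk2 -0.44 (SE 0.15) and Stat2 -0.24 (SE 0.09). The list passed camera (adjusted p = 2.7e-08) but not with an estimated correlation (adjusted p = 0.378), and its scores overlapped between the groups (exact permutation p = 0.2). Wild-type replicates 2 and 4 had the highest scores, 8.96 and 9.30. The same 2 arrays alone had high levels of Xist, the RNA of the inactive X chromosome, at 12.17 and 12.18, against 5.28 to 5.65 on the other 6. Their levels of the Y-linked gene Eif2s3y were 4.22 and 3.96, against 10.21 to 10.61 on the others. Such levels are those of female cells on these 2 arrays and of male cells on the other 6. Sex therefore appears unbalanced between the groups, although the labels give none. Without these 2 arrays, a comparison chosen after seeing the data, the interferon median was -0.050 and the call was lost (camera adjusted p = 0.194). The marginal zone median was then -0.36 and that of the B-1 and age-associated list 0.94, both still called.

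**Figure D3:**
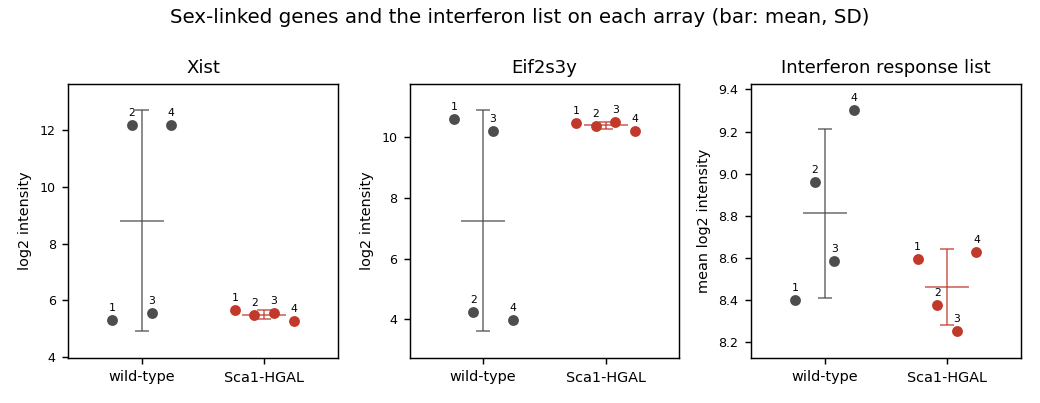
Log2 intensity of Xist and Eif2s3y and the mean log2 intensity of the interferon response list (vertical axes) on the 4 wild-type and 4 Sca1-HGAL arrays, with replicate numbers and bars for mean and SD. Wild-type replicates 2 and 4 have Xist at 12.17 and 12.18 and the highest interferon scores, 8.96 and 9.30.

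Other B-cell lists passed camera with smaller shifts, and none with an estimated correlation, where each had an adjusted p of 0.378 unless another is given. Transitional and immature B genes had a median of -0.05 and a mean of -0.24 (adjusted p = 0.0061), with Cd93 at -1.01, the transcription factor Myb at -0.99, Akap12 at -0.55 and Vpreb3 at -0.40. Follicular B genes had a median of -0.21 (adjusted p = 0.035), with Fcer2a, the IgE receptor CD23, at -0.42 and the homing receptor Ccr7 at -0.41. Germinal centre genes had a median of -0.09 (adjusted p = 0.038), with Rgs13 at -1.16 and Ezh2 at -0.41, and lost the call without the Xist-high arrays (median 0.00, adjusted p = 0.341). Receptor-proximal signalling genes had a median of -0.04 (adjusted p = 0.022), with Vav3 at -0.20, Dapp1 at -0.21 and Grb2 at 0.19. Syk had a log2 fold of 0.06 (SE 0.07, adjusted p = 0.83), Btk -0.10 and Blnk -0.08. B-cell identity genes had a median of -0.04 (adjusted p = 0.043, fry adjusted p = 0.041). Without the Xist-high arrays the median was no smaller in size, at -0.05, with an adjusted p = 0.056. Early activation genes had a median of -0.19 (adjusted p = 0.0061, and 0.554 with an estimated correlation), with Dusp5 at -0.43, Fosb at -0.42, Myc at -0.40 and Cd44 at 0.27. Cell cycle genes had a median of -0.09 (adjusted p = 0.011, and 0.668 with an estimated correlation), with Bub1 at -0.60 and Aurkb at -0.42. Their call was lost without the Xist-high arrays (median -0.06, adjusted p = 0.138). Heat shock and cell-handling genes had a median of -0.13 (adjusted p = 0.044, and 0.475 with an estimated correlation), with Hspe1 at -0.27. Of 21 alternative settings, the call was lost in 13 for germinal centre and for B-cell identity genes, 12 for follicular and for heat shock genes, 11 for cell cycle, 8 for receptor-proximal, 6 for early activation and 3 for transitional genes.

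Lists of other cell types moved in different directions. Neutrophil genes had a median of 0.34 with all 15 members positive, Elane at 0.40 and Mmp9 at 0.34 (camera adjusted p = 2.9e-05, and 0.378 with an estimated correlation). The most abundant members in wild-type arrays rose unevenly, with Fcnb at 0.06, Lcn2 at 1.00 and S100a9 at 0.11. Plasmacytoid dendritic cell genes had a median of -0.11, with Ccr9 at -0.83 and Siglech at -0.68 (adjusted p = 0.018, and 0.378 with an estimated correlation). These cells carry B220, and their call was lost without wild-type replicate 3 (adjusted p = 0.056) or 4 (0.058) or Sca1-HGAL replicate 3 (0.130). NK cell genes had a median of -0.11, with Gzma at -0.77 (adjusted p = 0.025, and 0.481 with an estimated correlation). Without the Xist-high arrays the call was lost (adjusted p = 0.123), but the median was -0.13, so this loss does not tie the shift to those arrays. Of 21 settings, the call was lost in 11 for NK cell, 7 for plasmacytoid dendritic cell and 4 for neutrophil genes. The macrophage and monocyte list did not pass (adjusted p = 0.97), although Adgre1, which encodes F4/80, had 1.01 (SE 0.19). Cd68 had 0.09, C1qb -0.18 and Lyz2 0.26, named after their values were seen. The T cell (adjusted p = 0.63), dendritic cell (0.88) and erythroid (0.47) lists did not pass. Among dendritic cell genes Tlr3 had -0.57, Clec9a -0.34, Flt3 0.41 and Zbtb46 0.22.

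**Figure D4:**
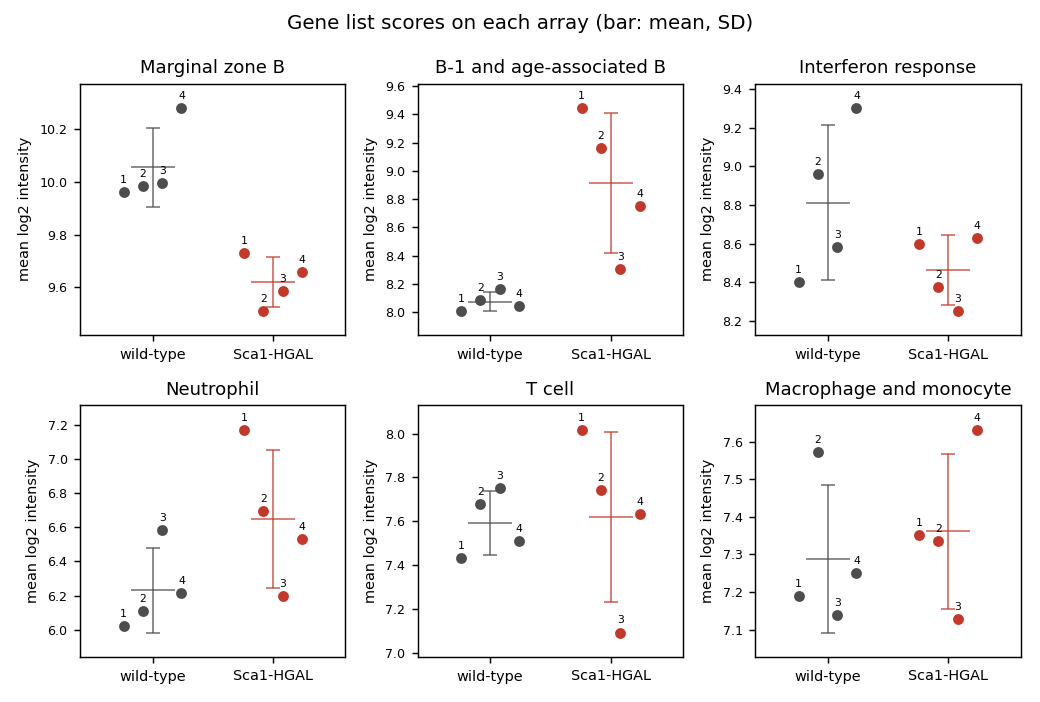
Mean log2 intensity (vertical axes) of the members of 6 gene lists on the 4 wild-type and 4 Sca1-HGAL arrays, with replicate numbers beside the points and bars for the mean and SD. The groups are apart for the marginal zone B and the B-1 and age-associated B lists and overlap for the other 4.

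The remaining lists did not pass camera. Among inhibitory regulators (adjusted p = 0.37), Fcgr2b, the inhibitory Fc receptor, had a log2 fold of 0.42 (SE 0.07) and Pirb 0.46 (SE 0.12). Among plasma cell genes (0.67), Slamf7 had -0.64, Sdc1 -0.43 and Txndc5 0.45. Among migration and adhesion receptors (0.42), Itgb1 had 1.15 and Cnr2 -0.29. Among BCL2 family genes (0.106), Bmf had -0.69, Bcl2l11 -0.43 and Bid -0.20. Among NF-kB targets (0.21), Tnfaip3 had -0.48, Rel -0.31 and Traf1 0.42. Among MHC class II and costimulation genes (0.147), Cd80 had 1.46, Ciita 0.14 and H2-Ab1 0.13. The 3 measured immunoglobulin constant regions (0.060) were Igha at -0.76, Ighg3 at -0.34 and Ighm at -0.16. Another probe set of Igha had -0.52, and further probe sets of Ighm had -0.04 and 0.06. The immunoglobulin list was called in 5 of 21 alternative settings, among them without the Xist-high arrays (median -0.37, adjusted p = 0.0086) and without wild-type replicate 4 (median -0.60, adjusted p = 0.023). Among RhoA and actin genes (0.88), Arhgef12 had 0.35 and Myl12b 0.18. Serum amyloid and acute phase genes (0.92) included Saa3 at -0.05 and Hp at 0.20. The lists of the unfolded protein response (0.88), glycolysis (0.47), oxidative phosphorylation (0.34) and cytosolic ribosomal proteins (0.92) also did not pass. The sex-linked list had a median of 1.61 (0.23). H2-Ea, at 0.02, and Nnt, at -0.18, whose expression depends on mouse strain, made up the list of strain differences (0.47).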

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

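The tests of other cell types and of the interferon list without the Xist-high arrays were chosen after the result was seen. A single array stood apart from its 3 group mates in 20 of 288 groups of 4 values checked, where chance gives about 14.4. In log2 levels, Sca1-HGAL replicate 1 was highest for Gzma (6.41), the cell cycle list (8.27, others 7.71 to 7.74) and the RhoA and actin list (11.42). Sca1-HGAL replicate 2 was highest for Adgre1 (9.36) and Cd22 (12.89). Sca1-HGAL replicate 3 was lowest for Lyz2 (7.67) and the glycolysis list (9.80) and highest for Uty (9.59) and the receptor-proximal signalling list (11.19). Sca1-HGAL replicate 4 was highest for C1qb (9.30) and Rtp4 (7.98) and lowest for the migration and adhesion list (10.51). Wild-type replicate 1 was highest for H2-Ea (13.94) and lowest for Igha (10.65), Itgb1 (8.49) and Txndc5 (9.10). Wild-type replicate 3 was highest for Myc (12.03). Wild-type replicate 4 was highest for Nod1 (8.81), Pik3r4 (10.65) and the marginal zone B list (10.28).

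Chance could not be excluded for the count of called probe sets or lists. Of the 35 splits of the 8 arrays into 4 and 4, 4 called at least the 1 probe set of the real split, and the highest other called 3. For lists, 3 splits called at least the real 14, and the highest other called 15. That split set wild-type replicates 1, 2 and 4 with Sca1-HGAL replicate 3 against the rest, so it kept both Xist-high arrays on one side. Leaving these 2 arrays out gave 10 lists in the real split. A further split that called 14 lists parted them, with wild-type replicates 1 and 2 and Sca1-HGAL replicates 3 and 4 against the rest. For probe sets with an unadjusted p under 0.05, 1 of the 35 splits, the real one, reached 2075, the smallest share 35 splits allow. This share is under 0.05, but the highest other gave 1992, and the other counts compared over the splits did not set the real split apart. Chance is therefore not excluded for this count either.

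The lower marginal zone B list and the higher B-1 and age-associated B list were weighed against the uneven sex-linked expression of the arrays. Without the 2 Xist-high arrays the scores stayed apart, but groups already apart cannot come to overlap when arrays are left out. The medians were then -0.36 and 0.94, against -0.45 and 0.95 with all arrays. Their size argues against that imbalance as the whole cause of either. The lower interferon list went the other way: its median without these arrays was -0.050, so its difference rests on those 2 arrays.

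Macrophages, T cells, NK cells and neutrophils, which a CD22 and B220 gate should remove, were weighed for the B-1 and age-associated B list, each expected to raise its own list score by at least 0.5 times as much, 0.419. The upper 95% bound of the score difference was 0.422 for macrophages and monocytes, 0.536 for T cells, 0.368 for NK cells and 0.998 for neutrophils, and with 0.5 times the B-1 score subtracted on each array, over members above log2 6, it was 0.098, -0.14, -0.090 and 0.404, where a value under 0 counts against the cell type. With the other score as a covariate, the list's difference of 0.84 (SE 0.25) was 0.81 (SE 0.28) for macrophages, 0.81 (SE 0.09) for T cells, 0.99 (SE 0.15) for NK cells and 0.45 (SE 0.16) for neutrophils. The share of 0.5 was a chosen bar, and a version that subtracted the full score had been looked at first. The first bound, 0.536 against 0.419, left T cells open, and the subtraction and covariate tests were added after that. Those later tests argue against T cells as the whole cause and, less firmly, against NK cells. The NK cell bound with the score subtracted was above 0 without wild-type replicate 2 (0.061) or 3 (0.032) or Sca1-HGAL replicate 3 or 4 (both 0.021). Macrophages stay open, since their score took up none of the spread as a covariate. Neutrophils, or something that varies with them, may account for part of the difference. Of the most abundant neutrophil list genes, however, Fcnb and S100a9 had log2 folds of only 0.06 and 0.11, and Lcn2 had 1.00. A B-cell effect of HGAL stays an untested hypothesis.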

How the results depend on the processing

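Leaving out the 2 Xist-high arrays, the Xist covariate and the permutation test of list scores were chosen after seeing the data. St3gal5 had a log2 fold between -1.92 and -1.76 and passed in 18 of 19 settings, with adjusted p from 0.000145 to 0.165, the latter in the ordinary test. The 24 genes named by p or fold kept their sign in all 452 values. As their groups did not overlap, leaving out arrays could not change it, so this was largely fixed by how they were chosen. Over all named genes, 27 of 2084 values changed sign, in 11 genes. Scaling moved the median of all probe sets by little (0.01 as deposited and after quantile normalisation, -0.02 when centred). Against 1 called probe set, there were 3 with centring (1 higher, 2 lower), 12 with array weights (6 and 6), 0 with the ordinary test, 2 without the Xist-high arrays (both lower), 9 at an adjusted p under 0.10 (3 and 6) and 118 at an unadjusted p under 0.01 with a 1.5-fold change (67 and 51). Leaving out 1 array gave 1 to 40, with 40 without Sca1-HGAL replicate 3, 2 without Sca1-HGAL replicate 1 and 2 without wild-type replicate 1. Against 14 called lists, there were 4 among probe sets above the median level, 0 with an estimated correlation and 2 with fry. The adjusted permutation test gave 0, but 8 arrays left it hardly able to call any list, so this decides nothing. Leaving out 1 array gave 7 to 16, with 7 without Sca1-HGAL replicate 2 or 4 and 9 without wild-type replicate 1 or 3. The marginal zone median ranged from -0.54 to -0.39 and the B-1 and age-associated median from 0.70 to 1.12 on leaving out 1 array, all called. The medians of -0.45 and 0.95 do not depend on the list test. The marginal zone list was not called with an estimated correlation (camera adjusted p = 0.264), nor the other list with this (0.378) or fry (0.115). Both lists had 0.189 in the adjusted permutation test, which could hardly have called them. The estimated correlations among members, 0.24 and 0.56, against the preset 0.01, widen the error. The NK cell list turned to 0.12 among probe sets above the median level, where 3 members were left, and the T cell list, at 0.01 with all arrays, ranged from -0.13 to 0.21 on leaving out 1 array and was called at 0.21 without Sca1-HGAL replicate 3 (adjusted p = 0.030) and at -0.13 without replicate 1 (0.018). The cause was not tested for the other changes. Of 649 values of the 31 lists other than these B-1 and marginal zone lists, 530 kept their status as called or not. Another 105 lost the call, 12 gained it and 2 reversed direction with a call. Values called in neither setting count as kept even where their direction changed. Over all 33 lists, 55 of 691 values changed direction.

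Equal replicate numbers did not pair the arrays: the correlations of same-numbered arrays ranged from -0.17 to 0.04, and 0 of 4 matched best with their own number. With the replicate block, 6 probe sets (4 higher, 2 lower) and 15 lists were called.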

Other observations

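All tests below on the Ifi200 paralogs were chosen after the result was seen. Several lymphocyte receptor and interferon-inducible genes that lie near each other on chromosome 1 (gene order of GRCm38.p6) were among the 200 genes with the smallest p. Of the 93 measured genes from Fcgr2b to Kmo, 10 were, 9 of them lower in Sca1-HGAL arrays. They were singled out after their values were seen. In the SLAM receptor cluster, Slamf1 had a log2 fold of -0.52, Cd48 -0.39 and Slamf7 -0.64. The cluster was not uniformly lower: outside the 200 genes, Slamf6 had 0.31 (SE 0.09) and Cd244a 0.05, and Ly9 -0.29 and Cd84 -0.24. In the Ifi200 cluster, Ifi206 had -1.77, Ifi213 -1.44, Ifi208 -1.20, Ifi209 -0.80 and Ifi203 -0.54. Kmo, an enzyme of tryptophan breakdown, had -0.54, and Fcgr2b 0.42. None passed limma's adjusted threshold. A run on chromosome 8 held Tti2, Fut10, Wrn, Rbpms, Saraf and Dusp4.

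A hypothesis is that the groups differ in which parental strain's copy of this stretch they carry, since the mice are of mixed CBA and C57BL/6J background. No genotype was analysed here, so it was not tested. Over all autosomes, chance could not be excluded for such grouping. The 200 genes held 33 close pairs, 2 of 35 splits gave as many, and the highest other gave 35. Pairs lay within 10 genes of each other and had symbols that differed in the first 3 letters. Relatives with unlike symbols, such as Cd48 and Slamf1, therefore counted, while pairs among the Ifi genes or of Slamf1 with Slamf7 did not. The count therefore says little about this stretch of chromosome 1, for which chance was not tested separately. Shuffling gene order gave a mean of 18.97 pairs (permutation p = 0.0025), but it ignores that neighbouring genes can vary together between mice, which the splits keep. Shared signal between Ifi200 paralogs would move them together, and 3 of the 10 moved the other way by over 2 SE. Of these, Ifi207 had 0.78 (SE 0.27), Aim2 only 0.14, and Ifi202b was at 4.55 in wild-type arrays, under log2 6. None of this excludes signal shared among the 5 lower genes alone. Of 83 genes of other families in the stretch, 5 were among the 200, where 0.87 are expected (exact binomial p = 0.0019). Since the ends of the stretch were set by such genes, this decides nothing. With the interferon score as a covariate, the mean of the 5 Ifi genes was -1.05 (SE 0.32, and -1.15 without), and without the Xist-high arrays the mean absolute fold of the 10 genes was 0.70 against 0.83. As these genes were picked for their small p, neither value excludes a lower interferon response or the uneven sex-linked expression.

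A second hypothesis was that further genes of age-associated B cells, not in the fixed list, would also be higher. Of 10 such genes written down before their values were seen, 9 had a positive log2 fold, with a median of 0.41, and 3 had an unadjusted p under 0.05: Sox5 (0.78), Lgals3 (0.44) and Pdcd1lg2 (0.54). The scores overlapped between the groups (exact two-sided permutation p = 0.114), so the test leaves the hypothesis open.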
